A study of Ovis aries with 6 samples.

How the data were processed

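Messenger RNA was measured by Illumina sequencing in 6 testis samples of Hu sheep, a Chinese breed of domestic sheep. Per the labels, 3 samples came from sheep on a maintenance energy diet and 3 from sheep on a 55% energy level. The labels do not state when the testes were taken, nor that each sample came from a different animal. The series title also names a compensation phase, for which no sample is labelled, so it stays open whether the restricted testes were taken during restriction or after it. The p-values therefore measure the spread between these samples. Each sample title is a letter that goes with the diet and a number that differs between all 6 samples. The labels do not call it a replicate number, so replicates were numbered in accession order, and their numbers do not pair samples across diets. Total RNA was isolated with TRIzol from frozen tissue, per the labels' protocols.

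A table of raw read counts per gene and a table of FPKM values (fragments scaled by gene length and library size) were deposited, each with 1 column per sample. TopHat2 and the sheep genome build Oar_v3.1 are named in the submitters' processing notes. The counter, the strand setting, the annotation release, any filter and the way unannotated genes were assembled are not given in the sources used here. Both tables hold 29307 genes, of which 20921 carry Ensembl sheep identifiers and 8386 carry identifiers of the form of Novel03527 and are called unannotated here. Every column name equals 1 sample title, and 0 columns were left unused. The deposited FPKM values were the counts divided by gene length and by the column total of the count table. For the 27955 genes with at least 1 count, that relation returned a length in whole bases, with the largest distance from a whole base 7.28e-11. The FPKM table thus holds no information beyond the counts and the gene lengths. Of the Ensembl lengths, 72.9% were multiples of 3.

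The reference table supplied for sheep pairs RefSeq genes with symbols, and 0 of the 29307 identifiers occurred in it. No gene name or coordinate was therefore assigned to any gene. The 33 lists of marker and pathway genes written before the data were examined could not be tested, and neither could the planned set of named genes. The naming rule fixed for this case was applied. It allows at most 2 identifiers in each direction, and those with the smallest p-value were taken. Outside this rule, 2 more identifiers are given, each named after its values were seen: ENSOARG00000005888 and Novel08062. Gene groups were instead defined after the data were examined, from what the files hold: the kind of identifier, the mean abundance and the gene length.

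Genes were kept by the default filter of edgeR 4.0.16 (filterByExpr, minimum count 10, minimum total count 15), which left 22323 genes, 15695 with Ensembl identifiers and 6628 unannotated. These held at least 99.8% of the counts of each library. Counts were scaled by the trimmed mean of M values (TMM) and compared between diets with the edgeR quasi-likelihood F test in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are given as restricted against maintenance on the log2 scale. Standard errors were taken from the F statistic, and 95% intervals from the moderated degrees of freedom. Values per library are CPM, counts scaled to a common library size. Gene groups were tested with camera in limma 3.58.1 on voom values, with an inter-gene correlation preset to 0.01 and again with an estimated correlation. Values per library were compared by two-sided exact permutation tests. With 3 libraries against 3, the smallest p such a test can give is 0.1.

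The test was checked on simulated counts for the 22323 genes of this comparison, drawn with the measured means, library sizes and spread, with 50 genes changed at each of 4 fold sizes. At the measured spread, 4 of 50 genes changed 2-fold were called, 13 of 50 changed 4-fold, 33 of 50 changed 8-fold and 46 of 50 changed 16-fold, with 6 false calls. Median estimated log2 changes were 1.06, 1.85, 3.02 and 4.11. With libraries simulated 4 times as deep, 2, 14, 33 and 45 of 50 were called. The simulation drew genes independently, without the differences that many genes share between these libraries. It changed no gene of low mean abundance, and its changed genes together eased the adjusted threshold for each one. These shares therefore need not hold for the measured libraries.

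Alternatives chosen before the data were examined were other scalings (RLE, upper quartile, library size only), no filter and a stricter filter (CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma-voom, robust edgeR, the edgeR exact test, other thresholds, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library in turn. For the FPKM fits a mean of at least 0.5 FPKM in either diet was required, except in the unfiltered fit. Added after the data were examined were the first principal component or 1 surrogate variable (sva 3.50.0) as a covariate, leaving out the 100 most abundant genes, Ensembl-identified genes alone, and DESeq2 on the genes kept by the edgeR filter. The planned DESeq2 run took all 27955 genes with at least 1 count, with its own filtering, so it changed the filter as well as the test. DESeq2 left the adjusted p of 79 genes undefined there and of 55 with the edgeR filter, and these were kept out of its counts.

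Libraries held between 13876765 and 20050430 counted reads. A count of 0 allows up to 3 reads, which is 0.150 to 0.216 CPM across the libraries. Intervals and limits of this kind cover counting error only and leave out the spread between samples. The labels name no molecular identifiers, so copies of one molecule may also count as separate reads. No pair of libraries agreed within sampling noise: over genes with at least 10 reads in the pair, the chi-square per degree of freedom was between 13.4 and 147. All 6 libraries were therefore counted separately.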

Results

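Testis RNA of Hu sheep kept at a maintenance energy level (n = 3) was compared with that of sheep kept at a 55% energy level, called restricted here (n = 3). The comparison addresses how dietary energy restriction alters gene expression in the testis. Maintenance libraries held 15513155, 20050430 and 17893995 counted reads, and restricted libraries held 15311385, 14885589 and 13876765. The means were 17819193 ± 2269562 and 14691246 ± 736791 reads (SD, n = 3). Every restricted library was shallower than every maintenance library, and the exact permutation p of 0.1 was the smallest this design allows (adjusted p = 0.333 over 10 values compared per library). A similar number of genes had at least 1 read: 26413 ± 142 in maintenance and 26370 ± 118 in restricted testes (exact permutation p = 0.7, adjusted p = 0.778).

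Pairs of testes were on average less alike within the maintenance diet, and more alike within the restricted diet, than pairs from different diets. The Spearman correlation of log2 CPM across the 22323 tested genes averaged 0.918 between maintenance testes (range 0.868 to 0.960) and 0.954 between restricted testes (range 0.943 to 0.975). Between the diets it averaged 0.942 (range 0.902 to 0.972). The mean within diets minus the mean between them was -0.00593, which did not pass a one-sided exact permutation test for a higher correlation within diets (p = 0.6 over 10 splits). Genes are not independent replicates in these correlations. Maintenance replicate 1 was closest to restricted replicate 2 (0.965), and maintenance replicates 2 and 3 were both closest to restricted replicate 1 (0.963 and 0.972). Restricted replicates 2 and 3 were closest to each other (0.975).

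The first principal component of log2 CPM carried 57.4% of the variance and ran across both diets. Maintenance replicate 1 (-89.6) and restricted replicates 2 (-54.7) and 3 (-47.1) lay on one side, and maintenance replicates 2 (106) and 3 (37.2) and restricted replicate 1 (48.5) lay on the other. Its mean did not differ between diets by more than the spread (17.8 ± 99.1 and -17.8 ± 57.5, SD, n = 3 each, exact permutation p = 0.7, adjusted p = 0.778). The second component carried 14.4% of the variance, with means of -25.8 ± 25.5 in maintenance and 25.8 ± 29.9 in restricted testes. All 3 restricted libraries lay above all 3 maintenance libraries on it (exact permutation p = 0.1, the smallest possible; adjusted p = 0.333). Across genes the median SD of log2 CPM was 0.478 in maintenance testes and 0.404 in restricted testes. Over maintenance replicates 2 and 3 alone the former was 0.234. An SD of fewer libraries is not on a par with these values. The same value without restricted replicate 1, which also lay apart from the rest of its diet on the first component, was not computed.

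**Figure D1:**
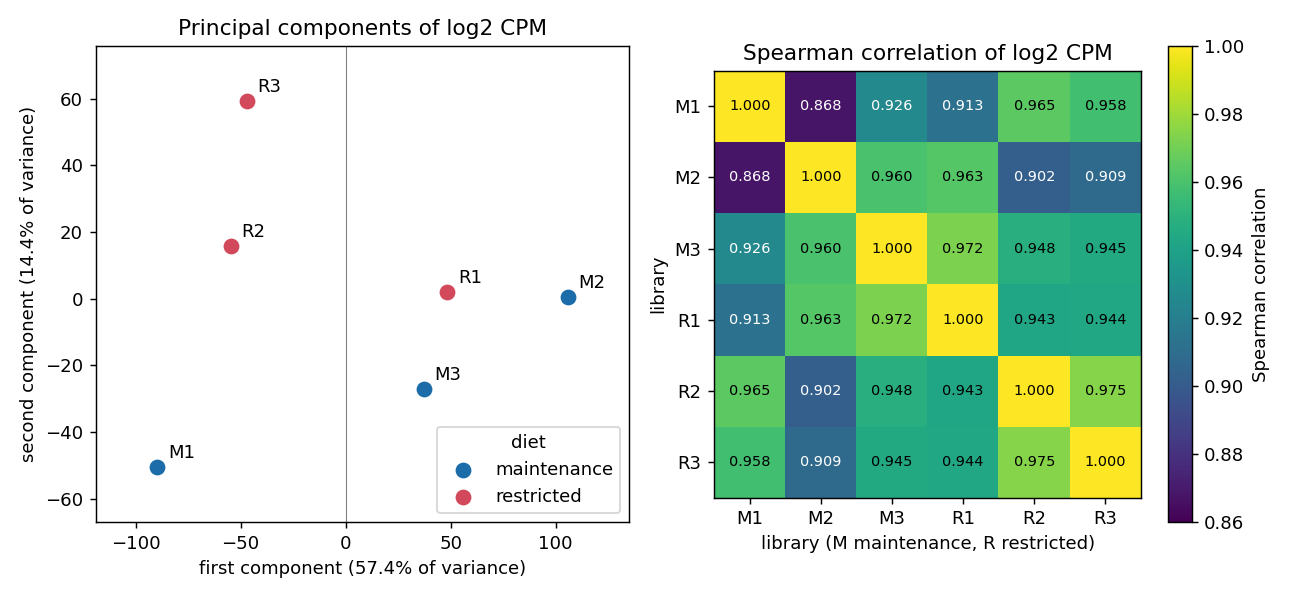
Left, each library by its first and second principal component of log2 CPM, coloured by diet, with M for maintenance and R for restricted; right, the Spearman correlation of each pair of libraries. Libraries M1, R2 and R3 lie below 0 on the first component and M2, M3 and R1 above it, and the lowest correlation is 0.868, between M1 and M2.

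No gene passed an adjusted p of 0.05 between restricted and maintenance testes in the edgeR quasi-likelihood test of 22323 genes, where the smallest adjusted p was 0.644. At an unadjusted p below 0.05 there were 540 genes, 104 higher and 436 lower in restricted testes. They made up 2.42% of the genes tested, where 5% would be below that value with no difference. The other splits of the libraries into 3 and 3 gave between 177 and 1008 such genes, except for 11041 in the split along the first component. A share under 5% thus does not mark the diets as differing less than other groupings. The number was 1915 with the first component as a covariate and 1947 with 1 surrogate variable. Without maintenance replicate 1 it was 2459 (1302 higher and 1157 lower). It was 1364 without restricted replicate 1, 290 without maintenance replicate 3, 305 without restricted replicate 2 and 232 without restricted replicate 3. On the first component, the restricted mean minus the maintenance mean was -35.6 with all libraries. It was -89.3 without maintenance replicate 1 and -68.7 without restricted replicate 1. Leaving out either library thus set the diets further apart along the crossing component, so the higher numbers do not by themselves show a response to diet. Of the genes at an unadjusted p below 0.05, the lower side held 80.7% with all libraries and 47.1% without maintenance replicate 1. It held between 58.3 and 78.4% without any other single library. The edgeR test without maintenance replicate 1 called 1 gene, lower in restricted testes. The limma-voom test also gave 0 genes, with 625 at an unadjusted p below 0.05, whereas DESeq2 on all genes with a count gave 12 (7 higher and 5 lower), DESeq2 on the genes kept by the filter gave 9 (6 higher and 3 lower) and the edgeR exact test gave 8 (5 higher and 3 lower). With library size alone as the scaling, 190 of 460 genes at an unadjusted p below 0.05 were higher and 270 were lower, and the median log2 change of all genes moved from -0.05 to 0.08. In 1413 genes (6.33%) the 3 restricted libraries lay wholly above (517) or below (896) the 3 maintenance libraries, where chance gives 10%.

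The precision set by the spread between testes was limited. The median absolute log2 change was 0.24 and the median standard error 0.41. The median 95% interval reached 0.97 to either side of the estimate. For 7284 genes (32.6%) the interval lay within a 2-fold change in both directions. For the remaining genes a 2-fold change was not excluded.

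**Figure D2:**
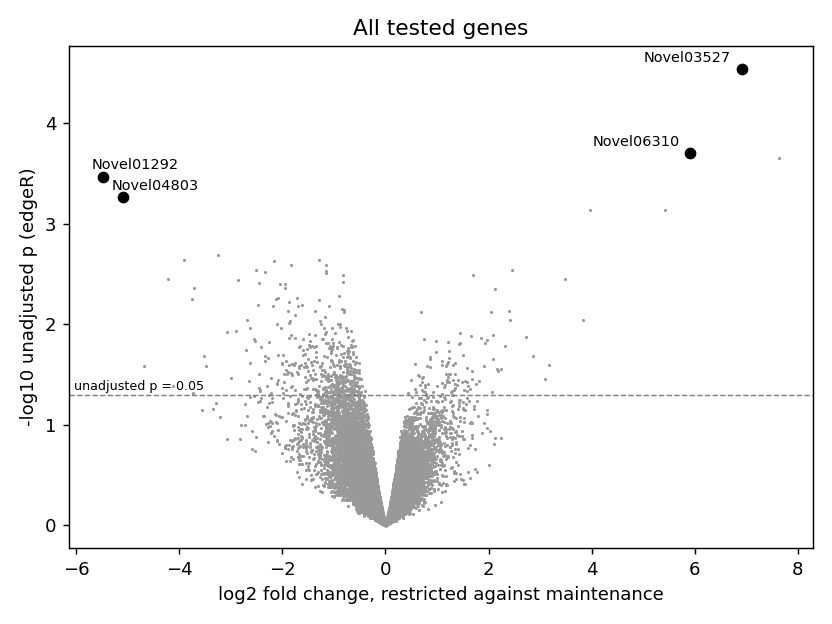
Each point is 1 of the 22323 tested genes, with its log2 fold change (restricted against maintenance) on the x axis and -log10 of the unadjusted edgeR p on the y axis; black points are the 4 genes with the smallest p in each direction, 2 higher and 2 lower. Above the dashed line, which marks the unadjusted threshold, 436 genes lie on the lower side and 104 on the higher side, and none passed after adjustment.

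Relative to all genes, abundant genes had lower estimates in restricted testes under each scaling run. A change of scaling shifts all genes nearly alike, so this relative value could hardly move between scalings. It did not stay lower without maintenance replicate 2 for genes of at least 100 CPM, and the edgeR test called none of the abundant genes singly. Of the 2511 genes with a mean of at least 100 CPM, 30.7% had a higher estimate in restricted testes, against 44.1% of all tested genes (52.8 and 59.3% with library size alone as the scaling), and 58 had an unadjusted p below 0.05, of which 58 were lower and 0 higher (37 lower and 8 higher with library size alone as the scaling). Their median log2 change relative to that of all genes was -0.07, and with library size alone as the scaling their own median was 0.017. For the 100 most abundant genes the relative median was -0.16, and 25% of them had a higher estimate (38% with library size alone as the scaling, where their own median was -0.07 against -0.21 with TMM). Camera placed both groups below other genes with the preset correlation (adjusted p = 0.000199 and 3.99e-05 over 9 groups), but not with an estimated correlation (adjusted p = 0.538 for both). None of these genes passed an adjusted p of 0.05, over all genes or adjusted over the list alone. Genes of at least 100 CPM took 59.9, 67.3 and 65.2% of the tested counts in maintenance and 65.2, 60.6 and 60.2% in restricted libraries, so their share went with the side of the first principal component and not with diet. Without maintenance replicate 2, which had the highest share, their relative median was 0.0053 and that of the 100 most abundant genes -0.08, and neither group passed camera. The relative medians were -0.24 and -0.39 without maintenance replicate 1 and -0.14 and -0.28 without restricted replicate 1. For the genes of at least 100 CPM it was also -0.04 without maintenance replicate 3 and -0.01 without restricted replicate 2.

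The gene with the highest mean CPM over the 6 libraries took 7945 ± 2054 CPM in maintenance and 4950 ± 3370 CPM in restricted testes (SD, n = 3, exact permutation p = 0.3, adjusted p = 0.6). The gene with the next highest mean took 5600 ± 3827 and 6703 ± 2167 CPM (exact permutation p = 0.7, adjusted p = 0.778), and it exceeded the former in maintenance replicate 1 and in restricted replicates 2 and 3. The 10 most abundant genes of each library took 3.67 ± 0.451% of its counts in maintenance and 3.31 ± 0.425% in restricted testes (exact permutation p = 0.5, adjusted p = 0.778).

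Unannotated genes, which carry no Ensembl identifier, took 6.35 ± 0.818% of the counts in maintenance and 6.43 ± 0.422% in restricted testes (SD, n = 3, exact permutation p = 1, adjusted p = 1). Of the 6628 unannotated genes tested, 201 had an unadjusted p below 0.05, 43 higher and 158 lower. Of the 15695 Ensembl genes, 339 did, 61 higher and 278 lower. The relative median log2 change of unannotated genes was -0.09. This difference passed camera with the preset correlation (adjusted p = 0.017) and not with an estimated correlation (adjusted p = 0.679). It was -0.31 without maintenance replicate 1, -0.29 without restricted replicate 1 and -0.04 without maintenance replicate 3. Without maintenance replicate 2 the relative median was 0.04, and without restricted replicates 2 or 3 it was -0.04 and -0.02, with no pass in camera in any of these fits. Of 3 equal classes of gene length, the shortest had a relative median of -0.04 and the longest of 0.05. Neither passed camera with the preset correlation (adjusted p = 0.060 and 0.054).

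The genes with the smallest p in each direction were unannotated genes with very few reads in one diet. Novel03527, with a gene length of 5193 bases, had 144, 151 and 69 reads in the restricted libraries and 0, 2 and 1 in the maintenance libraries, or 7.92 ± 3.02 and 0.056 ± 0.055 CPM (SD, n = 3). The ratio of the summed reads was 134 (95% exact interval 45.4 to 651, for counting error only). Its adjusted p was 0.644 with the edgeR quasi-likelihood test, 0.531 with limma-voom, 1.60e-08 with DESeq2 and 3.18e-11 with the edgeR exact test. Novel06310 (931 bases) had 67, 43 and 20 reads in restricted and 1, 1 and 0 in maintenance libraries, a ratio of 71.6 (interval 19.4 to 598). On the other side, Novel01292 (788 bases) had 17, 33 and 17 reads in maintenance and 0, 0 and 1 in restricted libraries, a ratio of 60.8 in favour of maintenance (interval 10.5 to 2438). Novel04803 (713 bases) had 11, 48 and 32 reads in maintenance and 1, 0 and 1 in restricted libraries, a ratio of 41.3 (interval 11.1 to 346). The adjusted p of each of these last 3 genes was 0.99998 with the edgeR quasi-likelihood test. In the order given, it was 0.999, 0.935 and 0.999 with limma-voom and 0.00301, 0.0851 and 0.0777 with DESeq2. The edgeR exact test gave adjusted p of 2.63e-05, 0.000186 and 0.00134. The position of these genes in the genome and their coding potential were not analysed here.

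**Figure D3:**
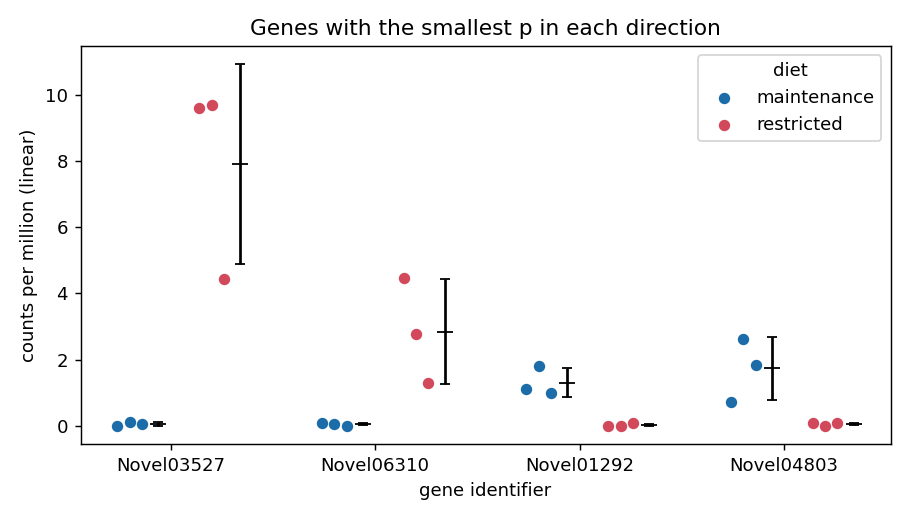
CPM of 4 genes in each library (points, coloured by diet), with the mean and SD of 3 libraries per diet beside them as a black bar. Novel03527 and Novel06310 lie near 0 in all 3 maintenance libraries, and Novel01292 and Novel04803 near 0 in all 3 restricted libraries.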

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

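The count of 0 genes past an adjusted p of 0.05 was kept under every scaling, filter, threshold, robust, voom, FPKM and covariate setting run. The exceptions were DESeq2 on all genes with a count, which changed filter and test together, with 12 genes (7 higher, 5 lower), DESeq2 on the genes kept by the edgeR filter, with 9 (6 higher, 3 lower), all 9 among the 12, and the edgeR exact test, with 8 (5 higher, 3 lower). The lists of 12 and of 8 shared 6 genes. Leaving out 1 library gave between 0 and 1 gene, with 0 higher and between 0 and 1 lower. The 1 call came without maintenance replicate 1, for ENSOARG00000005888 (adjusted p = 0.026, edgeR quasi-likelihood; named after its values were seen), which had 25, 601 and 565 reads in maintenance and 31, 22 and 23 in restricted libraries. The number of genes at an unadjusted p below 0.05, 540 with all libraries, was 2459 without maintenance replicate 1, 290 without maintenance replicate 3, 1364 without restricted replicate 1, 305 without restricted replicate 2 and 232 without restricted replicate 3. It was 495 without maintenance replicate 2. In the fits with 2459 and 1364 such genes, the diet means also lay further apart on the first component. Setting library size alone in place of TMM shifted all log2 changes by about 0.13. Leaving out 1 library moved the median log2 change relative to all genes between -0.31 and 0.037 for unannotated genes and between -0.24 and 0.0053 for genes of at least 100 CPM, with the sign turned without maintenance replicate 2, and between -0.39 and -0.08 for the 100 most abundant genes. The 4 genes with the smallest p in each direction, 2 higher and 2 lower, kept their direction in every setting that tested them. Their choice nearly fixed this, since each had at most 2 reads in every library of one diet. The filter of at least 1 CPM in 3 libraries left out Novel01292 and Novel04803, and Ensembl genes alone left out all 4. The exact test called all 4 and DESeq2 called 2 of them. No test of named gene lists was run, because no identifier could be paired with a name. In simulated data the spread limited the calls: at the measured spread 4 of 50 genes changed 2-fold and 46 of 50 changed 16-fold were called. With the dispersion divided by 4, 23 of 50 and 50 of 50 were. With libraries 4 times as deep at the measured spread, 2 of 50 and 45 of 50 were. The simulation drew genes independently and changed none of low mean abundance. Its changed genes together also eased the adjusted threshold for each one. These shares therefore need not hold for the measured libraries, and they do not tell why the edgeR test called 0 genes there. Novel03527 was not called in the measured libraries (adjusted p = 0.644, edgeR quasi-likelihood), although its summed reads differed by a ratio of 134.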

Other observations

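The tests of gene length, of abundant genes, of exchanged labels, of splits of the libraries and of genes read in one diet alone, and DESeq2 with the edgeR filter, were chosen after the results were seen. Those of depth and of the excess of DESeq2 calls were written before their own outcome, but the patterns they address had been seen.

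The abundance profile of the testes lined up with the sides of the first principal component. Genes with a mean of at least 100 CPM took 67.3, 65.2 and 65.2% of the tested counts in maintenance replicates 2 and 3 and restricted replicate 1, and 59.9, 60.6 and 60.2% in maintenance replicate 1 and restricted replicates 2 and 3. Genes between 10 and 100 CPM took 29.3, 31.1 and 31.1% in the former and 35.8, 35.3 and 36.0% in the latter. The gene with the highest mean CPM over the 6 libraries took 10114, 7689 and 8552 CPM against 6030, 4427 and 1873 CPM, and the gene with the next highest mean 2784, 4059 and 4847 against 9957, 9085 and 6176 CPM. These libraries are not groups of the study, and their values are given as they stand.

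The 6 libraries parted along a first component that crossed the diets, with 6.74% of its variance between them. Diet was not weighed as its source, because the pattern was chosen for crossing the diets. Thinning every library to the smallest total left 57.8% of the variance on this component (57.4% before), which argues against unequal sampling of reads as its source. Maintenance replicate 1 and restricted replicate 1, with 15513155 and 15311385 reads, lay on opposite sides of it. The deepest libraries, maintenance replicates 2 and 3 (20050430 and 17893995 reads), however shared a side. The shallowest, restricted replicates 2 and 3 (14885589 and 13876765 reads), shared the other. A factor that goes with depth was therefore not excluded. The 100 most abundant genes took between 11.2 and 13.5% of the counts of a library, a difference that can shift the other genes by at most 0.037 on the log2 scale, where their median range along the component was 0.90, which argues against a few genes taking the counts. Loadings did not follow the gene lengths that the FPKM values imply (Spearman rho = -0.036 across genes), which argues against a bias by those lengths. Whether they match the lengths of the full transcripts is not known.

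The real split of the libraries gave 0 calls, so each of the 10 splits into 3 and 3 had to give as many. This comparison therefore decides nothing, and the splits are also too few for a share under 0.05. The highest of the other splits gave 7598 calls. That split parts the libraries as the first component does, so its count restates this structure of the samples (the next highest split called 1 gene). It exchanges maintenance replicate 1 with restricted replicate 1. Any split other than the real one exchanges 1 library of each diet, so this form does not by itself point to exchanged samples. An exchange of these samples remains possible. The titles and column names of both go with their diet labels, which leaves open an exchange of the tissue, RNA or reads behind the titles. It cannot be told apart from a difference between testes unrelated to diet, such as their maturity or cell makeup, because no value in the tables identifies the animal behind a library and the genes carry no names.

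DESeq2 on all genes with a count called 12 genes where the edgeR quasi-likelihood test called 0. On the genes kept by the edgeR filter it called 9, and edgeR without a filter called 0. In 5 of the 9 other splits of the libraries DESeq2 gave at least as many calls, with a highest value of 9005 in the crossing split and between 12 and 16 in the others, and with the edgeR filter 6 of the 9 gave at least 9. Calls of this number thus also arise without the grouping by diet. An excess of the DESeq2 test at this spread may account for them, but so may real differences between samples, which these splits also hold. The edgeR exact test was not run on the splits. Of the 12 genes, 9 are unannotated and 5 had at most 3 reads in every library of one diet.

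Genes of at least 1 CPM in all 3 restricted libraries and at most 3 reads in every maintenance library numbered 3: Novel03527, Novel06310 and Novel08062 (the last named after its values were seen, with 28, 22 and 20 reads against 0, 0 and 0). There were 0 in the opposite direction, where Novel01292 came close to the limit. It had 1.12, 1.81 and 0.978 CPM in maintenance and at most 1 read in every restricted library. Among the 20 ways to choose 3 of the 6 libraries, 4 gave at least 3 such genes, the real one included, and the highest was 5 for maintenance replicate 3 with restricted replicates 1 and 2. A candidate explanation is therefore differences between single animals or samples, such as variants that remove or add a transcript. An effect of diet on these genes was not excluded. DESeq2 and the exact test called all 3 between the diets, and the edgeR quasi-likelihood test and limma-voom called 0. The genes were chosen for parting the diets, so these calls do not decide between the explanations.

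With the first component as a covariate, chosen after the data were examined, the edgeR test still called 0 genes, with 1915 at an unadjusted p below 0.05 and a smallest adjusted p of 0.112. Among the other splits fitted in the same way, the number at an unadjusted p below 0.05 was between 502 and 1752, and the highest number of calls was 1. The real split had the highest such number, but 10 splits are too few for a share under 0.05. The second component already parted the diets, so this rank may restate that order. Whether the first component hides a response to diet therefore stays open.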
